A study of Homo sapiens with 2 samples.

How the data were processed

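RNA of AGS cells stably transfected with an empty vector or with circ-CTNNB1 was made into libraries with the Illumina TruSeq RNA kit and sequenced on an Illumina instrument as 100 bp paired-end reads, per the labels. Alignment used TopHat2 2.0.9 with Bowtie2 2.0.6 on hg38, per the submitters' processing notes, and reads were counted per gene with HTSeq 0.6.0, per the series' design text. The gene annotation, the strand setting and the filter on genes were not given in the sources used here. Each sample had 1 deposited file of 26535 Ensembl gene identifiers with 1 value each. No row had fewer than 2 reads over both libraries.

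The deposited values are a signal per gene, gene counts scaled to a common library size, although the files are named for RPKM. Within a library, values were whole multiples of one amount for genes of any length, 0.906 per read for the empty vector and 1.10 for circ-CTNNB1, and the product of these amounts was 1.00. Whole reads, within 0.1 read, were recovered for 25624 of 25625 values above 0 with the empty vector and for 25071 of 25071 with circ-CTNNB1. The plan written before the data were examined assumed RPKM. To keep its thresholds, RPKM was computed here from the deposited values, the exon length of each gene in GENCODE release 29 (union of exons) and a common library size. That size was the arithmetic mean of the summed deposited values of the libraries. Of the rows, 26061 matched that annotation; 474 did not, held 0.0781% and 0.0967% of the values and were left out.

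The log2 ratio was log2((RPKM of circ-CTNNB1 + 0.1)/(RPKM of empty vector + 0.1)), which understates the difference of low genes, and genes were kept at a mean RPKM of at least 1 over both libraries. With 1 library per group no dispersion can be estimated, so no test across genes was run and no p-value is given for the groups. A 95% Clopper-Pearson interval was computed from the recovered reads of each gene. It compares those libraries, not the conditions, covers counting error only and uses no pseudocount, so for low genes the ratio can lie near its edge. The floor of 3 reads corresponds to 2.72 normalised counts with the empty vector and 3.31 with circ-CTNNB1.

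For 37 gene lists fixed before the data were examined, the median log2 ratio of the members was placed among 10000 random lists of the same size, drawn with replacement within 20 bins of mean RPKM, as a description of these libraries. Named genes followed a rule fixed at the same time: CTNNB1, DDX3X and YY1; the 12 highest and 12 lowest log2 ratios; the 5 highest and 5 lowest at a mean RPKM of at least 50; and the 2 highest and 2 lowest members of each list. Small or structural RNAs, clone-style and LOC names, XIST and Y-linked genes were left out of it. Small RNAs with Rfam-style names were left out by their annotated gene type, a reading of the rule made after the data were seen. Other genes named were chosen after their values were seen. Some members of the lists that the rule names, and the haematopoietic list, are not reported here.

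The alternatives were pseudocounts of 1 and 0.01, no filter, a mean RPKM of at least 5, an RPKM of at least 1 in both libraries, a TPM scale, centring on the median, trimmed mean of M values scaling, protein-coding genes only, thresholds of 1.5-fold and 4-fold, the counting interval as a further condition, and unmatched random lists. Random lists matched on GC content and expression, and log2 ratios less the median of their GC bin, were added after the data were seen. GC content is that of the longest annotated transcript of each gene. Random lists matched on expression and on GC content or exon length used 5 bins of mean RPKM and 10 of the other property.

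The procedures were tested on simulated Poisson reads for 26061 genes at the observed means and library sizes. For this comparison, 94.0% of 2-fold and 100% of 4-fold genes had an interval on the right side of equality. The 2-fold threshold was passed by 43.0% of 2-fold and 100% of 4-fold genes. Of 200 unchanged lists drawn at random, 5.50% fell outside the central 95%. The simulated genes varied independently, with counting error only and no trend with GC content. That share therefore does not show how often lists of genes that vary together fall outside. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.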

Results

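Sequencing libraries were made from total RNA of AGS cells, an established human gastric adenocarcinoma line, carried as puromycin-selected stable lines. One line held an empty vector and the other a construct for circ-CTNNB1, a circular RNA made from the CTNNB1 gene. Each group had 1 library. The empty vector library held 21877412 reads counted to genes and the circ-CTNNB1 library 17725738, spread over 26535 genes. Values are normalised read counts and, per kilobase of exon, RPKM. Ratios are log2(RPKM + 0.1) of the circ-CTNNB1 library minus that of the empty vector library. With 1 library per group there was no replicate check, and the 95% intervals (exact Clopper-Pearson) cover counting error only.

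The comparison asks how expression differed in cells labelled as overexpressing circ-CTNNB1. This circular RNA has been studied as a partner of the RNA helicase DDX3X and the transcription factor YY1 in beta-catenin signalling. CTNNB1, which encodes beta-catenin, had almost equal normalised counts of 6964 with the empty vector and 6861 with circ-CTNNB1, a log2 ratio of -0.02 (95% interval -0.07 to 0.03). The gene lies on chromosome 3 from 41194741 to 41260096 (GRCh38), and its count does not separate linear from circular or vector-borne transcripts. These counts therefore do not show whether circ-CTNNB1 was overproduced. DDX3X had 13525 and 13027 normalised counts, a log2 ratio of -0.05 (-0.09 to -0.02). YY1, on chromosome 14 from 100238298 to 100282792, was slightly higher with circ-CTNNB1, with 5086 against 4519 normalised counts and a log2 ratio of 0.17 (0.11 to 0.23). An interval that excludes equality was common in these libraries. Of 10589 coding genes with a mean RPKM of at least 1, 2712 had one above equality and 3837 below. The SD of the log2 ratio over those genes was 0.32.

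Protein-coding genes were largely alike in the libraries. Of 10589 coding genes with a mean RPKM of at least 1, 94.3% lay within 1.5-fold, 58 were at least 2-fold higher with circ-CTNNB1 and 18 at least 2-fold lower. Over all 13318 genes at that level the counts were 354 higher and 209 lower. Small or structural RNAs gave 146 and 91 of these, and the median number of reads behind a 2-fold gene was 21, against 1150 over all genes. When the counting interval also had to exclude equality, 196 genes were higher and 97 lower. Of 13099 genes simulated with no difference between the libraries, 113 came out 2-fold higher and 110 lower, of which 1 was protein coding.

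**Figure D1:**
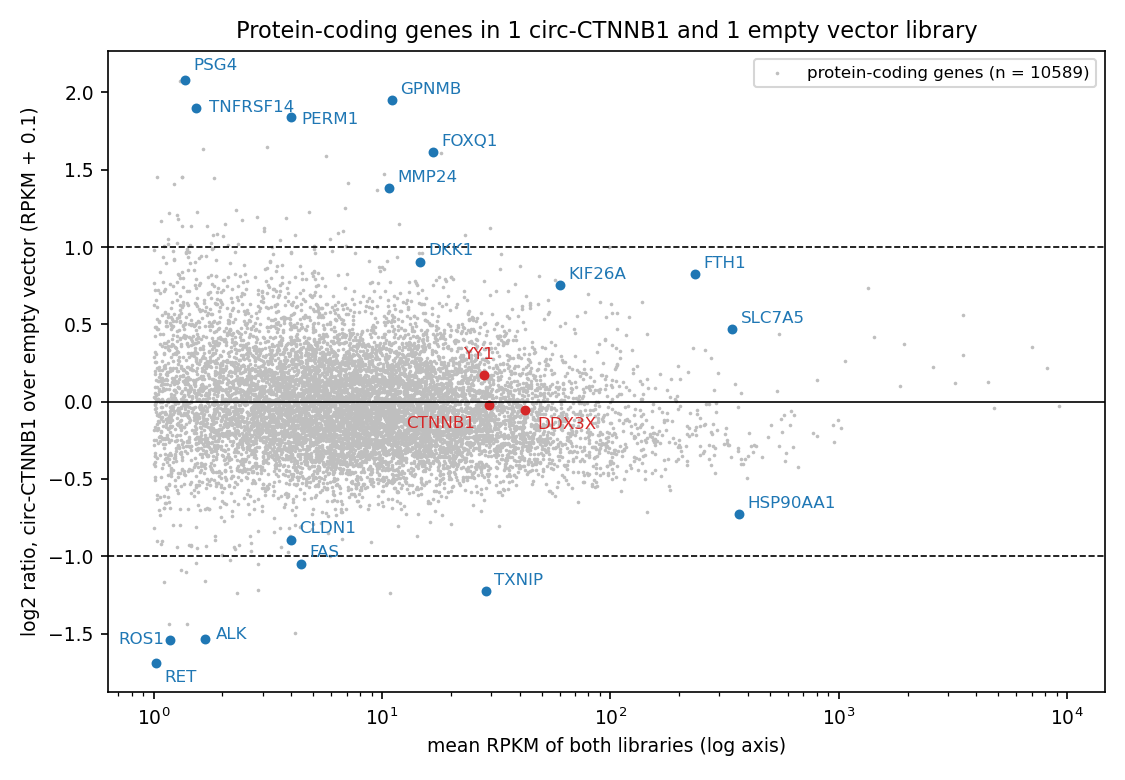
Each grey point is 1 of 10589 protein-coding genes, with mean RPKM on a log x axis and the log2 ratio of circ-CTNNB1 over empty vector on the y axis; dashed lines mark 2-fold. CTNNB1, DDX3X and YY1 (red) lie at -0.02, -0.05 and 0.17, while GPNMB lies at 1.95 and RET at -1.69; other named genes are blue.

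Among genes higher with circ-CTNNB1, GPNMB, a transmembrane glycoprotein of lysosomes and melanosomes, had 588 reads with the empty vector and 1898 with circ-CTNNB1, a log2 ratio of 1.95 (1.84 to 2.11). PSG4, a pregnancy-specific glycoprotein, was higher by 2.08 (1.90 to 2.72) and TNFRSF14, the receptor of the ligand LIGHT, by 1.90 (1.70 to 2.44). PERM1, a muscle regulator of mitochondrial genes, and KLHL38 had log2 ratios of 1.84 and 2.07. Under the naming rule, which leaves out small or structural RNAs and clone-style names, the highest value was that of IGFL1P1, a pseudogene of the growth factor-like gene IGFL1, with 138 and 858 reads and a log2 ratio of 2.91. It lies inside the noncoding gene IGFL2-AS1 (1.81) on chromosome 19, so reads of these overlapping genes may not be separable. The other highest names fixed by rule had few reads: ZNF29P, NDUFB1P1, SAPCD1-AS1, RPL23AP20 and UBE2FP3 had at most 26 reads in either library. Of genes with a mean RPKM of at least 50, the highest after IGFL1P1 under that rule were C19orf71 (1.00), the ferritin heavy chain gene FTH1 (0.82), the Notch-family repressor HES4 (0.79) and KIF26A (0.75). FTH1 had 169 RPKM with the empty vector and 299.6 RPKM with circ-CTNNB1.

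Genes lower with circ-CTNNB1 included several receptor tyrosine kinases. RET had 242 reads with the empty vector and 53 with circ-CTNNB1 (log2 ratio -1.69, -2.36 to -1.47), ROS1 had 309 and 78 (-1.54, -2.08 to -1.34), and ALK had 407 and 107 (-1.53, -1.96 to -1.33). FGFR2, named after its value was seen, had 258 and 87 (-1.165, -1.65 to -0.93). HSP90AA1, which encodes the inducible cytosolic HSP90 chaperone, was the lowest abundant coding gene, at 457 and 276 RPKM and a log2 ratio of -0.73 (-0.75 to -0.71). Most of the other lowest genes under the naming rule were pseudogenes; reads of a pseudogene and its parent may not be separable, which was not tested, so these values are uncertain. RPL7P1 (-1.52), CKS1BP3 (-1.52), RPL10AP6 (-1.61), EIF4EP2 (-1.66), HMGN1P36 (-2.33), MAP2K1P1 (-2.40) and RPL22P1 (-2.58) were among them, as were RPL39P3 (-1.31), EEF1A1P5 (-1.16), RPS28P7 (-0.92) and MTND2P28 (-0.81) at high expression. TRGJ1 had 4 reads and 0 reads and HIST1H2APS3 5 and 1. Chosen after their values were seen, TXNIP, an inhibitor of thioredoxin and glucose uptake, had a log2 ratio of -1.22 (-1.33 to -1.13), and its relative ARRDC4 -1.50 (-1.81 to -1.28).

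Wnt pathway components stood close to other genes of their expression at the planned minimum. Their median log2 ratio over 57 genes was 0.04, at the 91.4 percentile of 10000 random lists of the same size and expression, with 32 members above 0 and 25 below; at a mean RPKM of at least 5 it was 0.074, outside the central 95% (percentile 98.7). Within the list, the ligand WNT1 (1.63, from 22 and 61 reads) and the secreted Wnt inhibitor DKK1 (0.90, 0.75 to 1.08) were highest, and the receptor FZD10 (-0.87, -1.17 to -0.62) and the beta-catenin inhibitor CTNNBIP1 (-0.44, -0.76 to -0.16) lowest. Known beta-catenin/TCF target genes had a median of 0.17 over 21 genes, at the 98.8 percentile, but members went both ways, 12 above 0 and 9 below. BMP4 (1.03) and DKK1 (0.90) were highest, AXIN2, a negative-feedback target, stood at 0.78, and CLDN1 (-0.89) and FOSL1 (-0.64) were lowest; MYC was at -0.20 and CCND1 at -0.09. With genes of every expression level included the median of the targets was -0.025. After removal of the trend with GC content it was 0.058, at the 84.7 percentile, while against lists matched on GC content it lay at the edge of the central 95% (percentile 97.505). At a mean RPKM of at least 5 it was 0.28 (percentile 99.98).

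Cytosolic ribosomal protein, proteasome and mitosis genes were lower with circ-CTNNB1. All 47 cytosolic ribosomal protein genes had log2 ratios below 0, with a median of -0.29 (percentile 0.10), from RPL24 at -0.44 and RPL27 at -0.41 to RPS15 at -0.12 and RPL13 at -0.12. Proteasome subunits had a median of -0.34 (percentile 0), with 29 of 30 below 0; PSMB6 (-0.52) and PSMC6 (-0.51) were lowest, and PSMD3 (0.02) and PSMA2 (-0.13) highest. Mitosis genes had a median of -0.40 (percentile 0), with 33 of 35 below 0. MAD2L1 (-0.67) and TTK (-0.66), both of the spindle checkpoint, were lowest, while the proliferation marker MKI67 (0.01) and the mitotic transcription factor FOXM1 (0.05) were near equality. DNA replication genes, at a median of -0.12 (percentile 25.6), lay within the random range, from RFC3 (-0.42) and POLA1 (-0.38) to E2F1 (0.51) and GINS3 (0.85). Replication-dependent histones had a median of -0.29 (percentile 0.41; 16 genes), with HIST1H2BC (-1.24) and HIST1H2BJ (-0.64) lowest, and HIST1H3B (0.75) and HIST4H4 (0.75) highest.

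Targets of p53 were also lower, with a median of -0.29 (percentile 0.03) and 21 of 27 below 0. The death receptor gene FAS had a log2 ratio of -1.05 (-1.31 to -0.84) and the antiproliferative gene BTG2 -0.99 (-1.37 to -0.69), whereas PHLDA3 (0.25) and BBC3 (0.15) were highest. Nuclear-encoded respiratory chain genes had a median of -0.21 at the 2.75 percentile, with 39 of 43 below 0; NDUFB5 (-0.54) and COX6A1 (-0.51) were lowest, and NDUFV2 (0.48) and NDUFV1 (0.20) highest. By contrast, the 13 mitochondrially encoded mRNAs had a median of 0.22 (percentile 99.99), led by MT-ND1 (0.56) and MT-ND6 (0.42), with MT-CO2 (-0.03) and MT-ATP6 (-0.04) lowest. Reads of the mitochondrial chromosome were 5.73% of the empty vector library and 6.89% of the circ-CTNNB1 library. The unfolded protein response list, at -0.21 (percentile 3.33), had MANF (-0.63) and SELENOK (-0.66) lowest, and ERN1 (0.28) and HERPUD1 (0.27) highest.

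Several signalling and metabolic lists were higher with circ-CTNNB1. Hippo/YAP target genes had a median of 0.26 (percentile 99.99), with 18 of 25 above 0; ANKRD1 (0.85) and LATS2 (0.78) were highest, and F3 (-0.31) and FJX1 (-0.21) lowest. Hypoxia and glycolysis genes had a median of 0.16 (percentile 99.97), with the carbonic anhydrase gene CA9 highest (95% interval 0.71 to 1.59) and the vasodilator peptide ADM at a log2 ratio of 0.91, against LDHB at -0.40 and P4HA1 at -0.36. Cholesterol biosynthesis genes, at 0.15 (percentile 99.9), included the lanosterol synthase gene LSS at 0.43, with FDFT1 (-0.30) and PMVK (-0.25) lowest. The TGF-beta and BMP list, at 0.15 (percentile 99.5, or 95.2 with genes of every expression level), had BMP4 (1.03) and ID2 (0.97) highest, and SMURF2 at -0.31 among the lowest. NF-kB and cytokine genes had a median of 0.17 (percentile 97.9), with PTGS2 (0.73) and TNFAIP3 (0.68) highest, and NFKBIE (-0.43) and BIRC3 (-0.41) lowest; they stood at the 89.8 percentile when matched on GC content as well, and at the 88.0 percentile at a mean RPKM of at least 5. Gastric lineage genes had a median of 0.61 (percentile 99.8) over only 5 genes, among them the forkhead factor FOXQ1 (1.61), the mucin MUC1 (0.86), GATA6 (0.53) and MUC5AC (-0.21); with genes of every expression level the median was 0.095, at the 73.5 percentile.

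**Figure D2:**
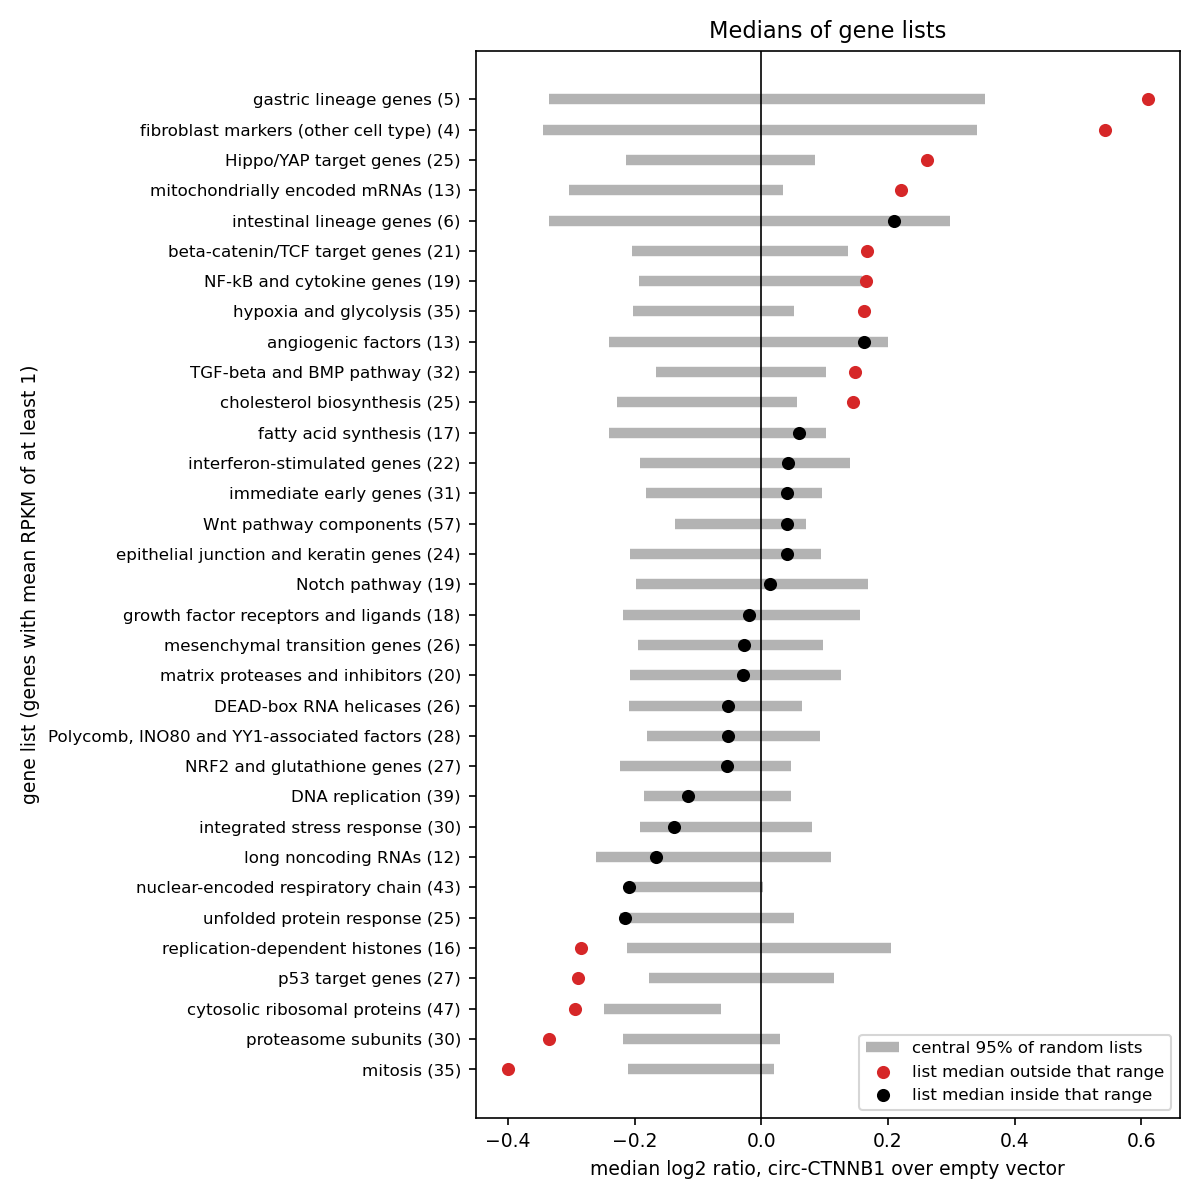
For each gene list with at least 4 genes at a mean RPKM of at least 1, the point is the median log2 ratio of circ-CTNNB1 over empty vector and the grey bar the central 95% of 10000 random lists of like size and expression. Mitosis genes lie lowest at -0.40 and gastric lineage genes highest at 0.61; red points lie outside their bar.

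The other lists lay within the central 95% of random lists. Medians were -0.05 for Polycomb, INO80 and YY1-associated factors (RUVBL1 at -0.50, TFPT at 0.47), -0.05 for DEAD-box helicases (DDX50 at -0.48, DDX39B at 0.35) and -0.14 for the integrated stress response (STC2 at -0.57, SLC7A5 at 0.47). Epithelial junction and keratin genes stood at 0.04, with EPCAM (-0.66) and KRT81 (0.97), and mesenchymal transition genes at -0.03, with ZEB1 (-0.80) and COL1A1 (0.84). Growth factor receptors and ligands had a median of -0.02, although RET and ROS1 were its lowest members, and PDGFRB (0.74) its highest. Immediate early genes stood at 0.04, with EGR1 at -1.09 and DUSP1 at 0.81, and the Notch list at 0.01, with NOTCH3 at -0.67 and MFNG at 0.82. Matrix proteases had a median of -0.03 (MMP24 at 1.38, TIMP4 at -0.65), angiogenic factors 0.16 (ADM at 0.91, ANGPTL4 at -0.93), intestinal lineage genes 0.21 (KRT20 at 0.66, ANPEP at -0.21) and interferon-stimulated genes 0.04 (IFIT3 at 0.49, SAMD9 at -0.44). Fatty acid synthesis stood at 0.06 (LPIN1 at 0.66, ACSL4 at -0.39), NRF2 and glutathione genes at -0.05 (FTH1 at 0.82, AKR1C2 at -0.57) and 12 long noncoding RNAs at -0.17, with MALAT1 at 0.48 and SNHG5 at -0.65. In all, 14 of the 36 lists with a median lay outside the central 95%, lists share genes, and a list can do so by chance.

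Markers of other cell types were few. Of fibroblast markers, 4 genes passed the expression minimum, with a median of 0.54 (percentile 99.7, or 74.7 with genes of every expression level): COL1A1 (0.84), PDGFRB (0.74), FBLN1 (0.34) and TWIST1 (0.17), whereas DCN had 316 reads with the empty vector and 183 with circ-CTNNB1. A single endothelial marker (ESAM, -0.07) and a single neuroblastoma marker (GATA2, 0.01) reached a mean RPKM of 1, and no hepatocyte marker did, with 26 and 9 reads over all of them.

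Across protein-coding genes the log2 ratio went with the GC content of the exons (Spearman rho 0.42 across 10589 genes, which are not independent replicates). The median was -0.21 in the tenth of genes with the lowest GC and 0.18 in the tenth with the highest.

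**Figure D3:**
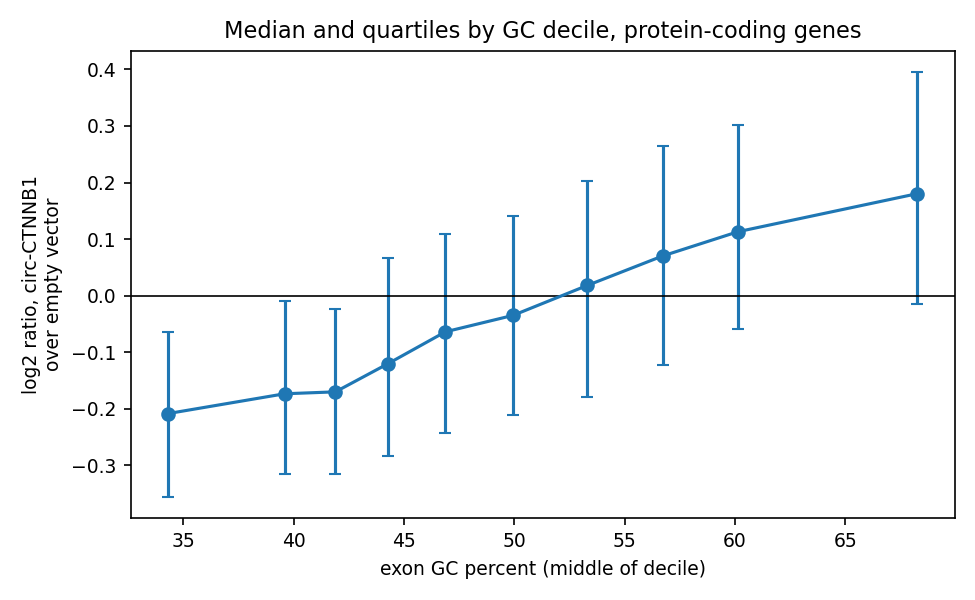
Points are medians and bars quartiles of the log2 ratio of circ-CTNNB1 over empty vector (y axis) in 10 groups of protein-coding genes by exon GC percent (x axis). The medians go from -0.21 at the lowest GC to 0.18 at the highest.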

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

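The GC-based alternatives were chosen after the data were seen. No paired analysis was possible because each group holds 1 library. Counts of 2-fold genes, 354 higher and 209 lower, stayed within 1.5 times of these under a pseudocount of 0.01, the scalings and removal of the GC trend, and moved further elsewhere. They were 151 and 85 with a pseudocount of 1, 1693 and 1528 with no filter, 56 and 32 at a mean RPKM of at least 5, 166 and 86 with an RPKM of at least 1 in both libraries, and 58 and 18 for protein-coding genes. The 1.5-fold threshold gave 1075 and 562, the 4-fold threshold 62 and 31, and the added counting interval 196 and 97. By construction, keeping fewer genes or a stricter threshold can only lower the counts, and the reverse can only raise them. The number of genes kept does not account for the size of the changes. Coding genes were 10589 of the 13318 genes but gave only 58 of the 354 higher and 18 of the 209 lower. The pseudocount of 1 also lowers the counts by construction, since it brings every ratio closer to equality. CTNNB1 stood at 0.074 less the median of its GC bin. The Wnt components had a median of 0.074 at a mean RPKM of at least 5, at the 98.7 percentile. The beta-catenin/TCF targets changed sign with no filter (-0.025, percentile 47.4), where low genes enter, and fell inside the central 95% against unmatched lists (0.17, percentile 97.3) and less the GC trend (0.058, percentile 84.7); the cause was not tested. Of 1459 alternative values of named genes, 1385 stayed within counting error and 74 moved beyond it, with none of opposite sign among 2-fold genes. Alternatives that change only which genes are kept leave the ratio of a gene as it is, so those values could not move. Removal of the GC trend gave 53 of the 74 moves, while 104 named genes stayed within counting error under it. Of 406 alternative values for other lists, 361 were the same, 25 moved, 12 went outside the central 95% and 8 came back inside, and none of those outside it at first changed sign. Those that came back were NF-kB genes (percentile 88.0 at a mean RPKM of at least 5, 97.3 unmatched, 89.8 matched on GC, 79.6 less the GC trend), gastric genes (73.5) and TGF-beta and BMP genes (95.2) with no filter, and fibroblast markers (74.7 with no filter, 96.2 at a mean RPKM of at least 5). Those that went outside were nuclear-encoded respiratory chain genes in 5 alternatives, angiogenic factors in 2, and the integrated stress response, unfolded protein response, fatty acid, immediate early and Notch lists in 1 each. Depth limits genes of few reads most.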

Other observations

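The tests of GC content and exon length on gene lists, of GC content on ALK, RET and ROS1, of dividing cells, of tumour sequencing panels, of neural crest or stromal markers and of lysosomal genes were chosen only after values they use had been seen. Genes of lysosomes stood out among those higher with circ-CTNNB1. Beside GPNMB, they included GRN, the progranulin gene (0.69, 0.64 to 0.75), FLCN, the folliculin gene (1.12, 0.98 to 1.34), and the protease gene CTSD (0.60). A hypothesis is that the lysosomal programme of the transcription factors TFEB and TFE3 was more active in these cells. A list written for this programme also held genes not of lysosomes, such as HIF1A. With GPNMB, GRN, FLCN, CTSD and FTH1 left out, its other 45 genes had a median log2 ratio of 0.20. This was the 99.99 percentile of random lists matched on expression and GC content. Without CLCN7, CTSB and CTSL as well, 42 genes stood at 0.21 (percentile 100). Of the 45, 27 had a counting interval above equality and 6 below, such as HIF1A (-0.30), ATP6V1A (-0.23) and UVRAG (-0.21). Over all 13318 genes at the expression minimum, 3217 had one above equality and 4055 below. The activity of the factors themselves was not measured.

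Single genes chosen after their values were seen included TXNIP at -1.22, ARRDC4 at -1.50 and ARRDC3 at -0.94 (-1.20 to -0.73). They also included the chaperone genes HSP90AB1 at -0.33, HSPD1 at -0.57 and HSPA8 at -0.22. No gene list holding them was tested.

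The lower mitosis, proteasome and ribosomal protein genes are a pattern that GC content or exon length might produce, since the log2 ratio went with both. Against random lists matched on expression and GC content, the highest percentile of the 3 lists was 0.01, and with matching on exon length it was 0. This argues against GC content and exon length, as annotated, as the whole cause. GC content was that of the longest transcript and length the union of all annotated exons, such as 6172 bp for RPL13. Trends with the GC content or length of the transcripts expressed therefore stay open. A smaller share of dividing cells stays open. Each less its GC-matched random median, replication genes lay 0.19 above mitosis genes (bootstrap interval 0.08 to 0.38). The bootstrap resampled the genes of each list, so it covers spread over genes and not between cultures. Replication-dependent histones were lower, at -0.29 and the 0.05 percentile of GC-matched lists, or 2.35 with matching on exon length. Some histone genes had few reads, such as HIST1H2BC with 60 and 20 and HIST1H3B with 12 and 17, which limits what that list can decide. Effects of circ-CTNNB1 and differences between the stable lines in density or handling stay open, with 1 library each.

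Medians were 0.26 for 497 lincRNA genes, 0.24 for 664 antisense genes and 0.24 for 144 sense-intronic genes, against -0.05 for coding genes. Transcribed unprocessed pseudogenes (0.11) and, from few reads, snRNA (0.27), snoRNA (0.12) and miRNA genes (0.53) were also higher than coding genes. Medians were -0.21 for 389 processed pseudogenes, -0.04 for 131 miscellaneous RNAs and -0.17 for the list of 12 long noncoding RNAs fixed in advance. The lower percentile of the lincRNA and antisense classes among random coding lists matched on expression and GC content was 100, against those properties as the cause. Genomic DNA in the circ-CTNNB1 library would raise reads over genes with little or no transcription. The 39 olfactory receptor genes had 343 reads with the empty vector and 226 with circ-CTNNB1, a normalised log2 ratio of -0.32 (-0.57 to -0.07), or -0.39 (-0.70 to -0.09) without OR7E38P, which held 108 and 79 of these reads and may be transcribed; this argues against it. Sense-intronic genes lay at percentile 100 of coding lists matched in the same way, whose median was -0.06. A difference in nuclear or unspliced RNA between the libraries was not tested.

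ALK, RET and ROS1, the 3 lowest coding genes, had 0.26, 0.22 and 0.25 reads with circ-CTNNB1 per read with the empty vector. GC content is argued against, since less the median of their GC bin the highest of the 3 log2 ratios was -1.41, with upper counting bounds at or below -1.21. Cells of a neural crest or stromal type in the empty vector culture stay open, since markers went both ways: 3 of 19 had an interval below equality (DCN at -0.46, CHRNA3 at -0.94 and PDGFRA at -1.12) and 4 above it (COL1A1, PDGFRB, FBLN1 and ISL1). Carried-over reads of a tumour sequencing panel are possible. Without ALK, RET and ROS1, 11 rearrangement panel genes with a mean RPKM of 0.1 to 3 stood at -0.75 (percentile 0) and 16 hotspot panel genes at -0.28 (percentile 0.32). With those genes included, 13 of 14 rearrangement and 14 of 18 hotspot genes were below 0. The interval was below equality for 11 and 10 of them, while STK11 of the hotspot panel stood at 0.40 (0.19 to 0.64). Both lists were written down after many of the values were known, and they overlap. Beside ALK and RET, both hold BRAF, FGFR1, FGFR2, KIT and PDGFRA at this expression level, and PDGFRA is also among the markers above. Yet 13 other receptor kinases, outside these panels, stood at -0.52 (percentile 0.04), with 8 of 13 below 0 and EPHA7 at 0.41 (0.11 to 0.81), so carry-over cannot be told apart from lower expression of some such receptors.

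Genes are listed in the files in order of their ratio. MYCN and WNT4 were the only 2 of 26515 rows whose log2 ratio, here of the deposited values plus a small constant and not of RPKM, lay over 0.1 from the median of the 21 rows around them. The MYCN value with the empty vector, 8.87, was also the only one that was not a whole number of reads, 2.00 below the value of 12 reads. WNT4 had 14 and 15 reads, a ratio of these values of 1.30, not on the log2 scale, among neighbours at 2.10. The cause was not tested, and both genes are below the expression minimum.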
